A study of Homo sapiens with 4 samples.

How the data were processed

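The series maps γH2AX by CUT&Tag in HepG2 cells, with 4 samples in 4 groups of 1 sample each: mock-treated and lipid-overloaded cells with the γH2AX antibody, and the same with control IgG. Groups were taken from the sample titles. Each assay used 100000 cells and 14 PCR cycles, per the labels. Per the submitters' processing notes, FastQC, BWA, MACS2 2.1.2 and deepTools were used with genome build hg38. Their settings, and whether an IgG library served as control in peak calling, are not given in the sources used here.

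The 2 files used are peak lists, 1 per γH2AX library, so peaks were called per sample. In the deposited lists each peak has a position, a score, a fold enrichment at the summit, −log10 p, −log10 q and the summit offset. The fold (a linear ratio), the score and the −log10 values are the authors' own, as deposited, and served here only to describe, rank and filter peaks within a list and to recover fragment numbers. The lowest −log10 q was 1.30 in both lists, and no interval was repeated. The IgG samples were not analysed here, so no background measured in the same way stands beside the values.

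The deposited fold and −log10 p of a peak were solved together for the number of fragments over the summit and the local background, under the formulas of MACS2: fold is fragments plus 1 over background plus 1, and p is the Poisson tail above the fragment number. A whole number of fragments fitted 100% of the peaks in both lists within 0.0001 in log10 p. Tested on simulated data, the step returned the true number for 100% of 8542 mock-like peaks and 99.996% of 27296 lipid-like peaks. The lowest background, taken as that of the genome, stood at 9.51% of the mock and 7.42% of the lipid-overload peaks. Above it, the local backgrounds of the 7698 mock and 25119 lipid-overload peaks with fewer than 60 fragments all lay within 0.1 of a step of whole multiples of 0.00684 (mock) and 0.00622 (lipid overload), which is a mean fragment length of 137 and 124 bp when 2 fragment ends in 10 kb are counted. This genome background was 0.121 and 0.289 fragments. Divided by fragment length, it gives 2.62 times as many fragments in the lipid-overload library. Intervals are exact Poisson for fragment numbers and exact binomial for shares, at 95%, and cover counting error only, since PCR copies are not independent molecules.

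Genes came from the NCBI RefSeq gene table of GRCh38.p14, the same coordinates as hg38. The table holds positions but no strand, transcripts or sequence. The planned promoter, 1 kb around the 5′ end, was therefore replaced by a gene end, 1 kb either side of either end of a protein-coding gene. Results on exons, introns, G+C, CpG islands, repeats and G-quadruplexes were not run, nor were the alternatives that need transcripts or a repeat mask, the matching of random lists on CpG content, or a planned test of CpG-rich promoters. Of 59788 table genes, 718 (171 protein-coding) break the position order of their chromosome by over 1 Mb, as genes on other scaffolds do, and were set aside. This filter was chosen after a first run had shown the results. It left 19817 protein-coding genes on chromosomes 1 to 22 and X. The 5′ end was taken as known for 556 genes with a divergent transcript, named after the gene, within 2 kb.

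Peaks were called overlapping when they shared at least 1 bp. Overlap was computed in numpy in place of bedtools, by the same definition. Expected shares came from 100 shuffles of peaks within their chromosome, over 1 Mb windows that hold a gene or a peak, in place of a map of assembly gaps. Before the data were examined, 15 gene lists with 315 genes were fixed, all of which were found in the table. Each list's count of genes with a gene-end peak, and with a peak anywhere in the gene or at its ends, was placed among 10000 random lists matched on gene length in 20 bins. The percentile describes these libraries and is not a test. Random lists were not matched on expression, which was not analysed here.

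Named genes followed a rule fixed before the data were examined, by rank on −log10 q, then fold. It took the 10 genes with the highest peaks found only in lipid overload, the 8 best-ranked in both lists, the 5 highest found only in mock, the 6 genes with most lipid-only peaks, the 5 highest lipid-only peaks away from gene ends, and up to 4 members of each list marked only in lipid overload, or 2 marked in both. Further list members were named after their values were seen, among them LSS, INSIG1, DHCR7, SC5D, HSPA5, TP53I3, ALB, APOB, HNF4A, DLG2, NRXN3, FHIT and CNTNAP2, as were the genes placed in dense windows. Some list members that the rule names are not reported here.

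The alternatives planned were a −log10 q of at least 5, a fold of at least 5, equal list lengths, peaks within 1 kb merged, overlap of 50% of each peak or within 1 kb, gene ends of 3 kb, and random lists without matching. The number of genes marked only in lipid overload does not use the overlap of peaks, so the overlap rules were not run on it. Chosen after seeing the data were leaving out peaks within 1 Mb of a chromosome end, and thinning the lipid-overload library to the mock depth. In thinning, the fragments of each summit and of its local background were drawn binomially at 38.1%, and peaks were kept at the lowest −log10 p of the mock list. Thinning can only drop listed peaks and cannot add weak ones that a shallower library would list. Unless called a range over the draws, the interval of a thinned ratio joins that range with the counting interval of the mock number. Tested on simulated data, 2000000 sites with equal rates in both libraries gave thinned to mock ratios of 0.952 to 0.965 over 5 runs.

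Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. With 1 library per group no test between conditions was possible, and no p-value is given.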

Results

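Sites of γH2AX, the histone variant H2AX phosphorylated at serine 139 and a marker of DNA double-strand breaks, were mapped by CUT&Tag in HepG2, a human liver cancer cell line. CUT&Tag tethers a transposase to an antibody bound to chromatin, so that DNA near the antibody is cut and tagged for sequencing. The series holds 4 samples in 4 groups of 1 sample each: mock-treated and lipid-overloaded cells, each with the γH2AX antibody and with control IgG. Peak lists of the 2 γH2AX libraries were analysed, and the 2 IgG samples were not analysed here. With 1 library per condition there is no replicate check on any difference. Each interval below is a 95% interval covering counting error only, except for thinned values. Those have the range over the draws, for ratios joined with the counting interval of the mock number unless called a range.

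The mock list held 8542 peaks and the lipid-overload list 27296. Peaks were narrow in both, with a median width of 180 bp in mock and 196 bp in lipid overload, and covered 1.78 Mb and 6.63 Mb. The number of fragments over each summit, worked out from the authors' fold and p values, had a median of 5 in mock (quartiles 4 and 8) and 9 in lipid overload (quartiles 6 and 13). In mock, 55.3% of the peaks rested on 5 fragments or fewer, against 18.6% in lipid overload. The background levels in the files put the lipid-overload library at 2.62 times the fragments of the mock library. Unequal depth by itself changes peak numbers, so values with the lipid-overload fragments thinned to the mock depth are also given for the peak number, the overlaps, the gene-end shares and most gene counts. Thinning was chosen after the data had been seen.

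**Figure D1:**
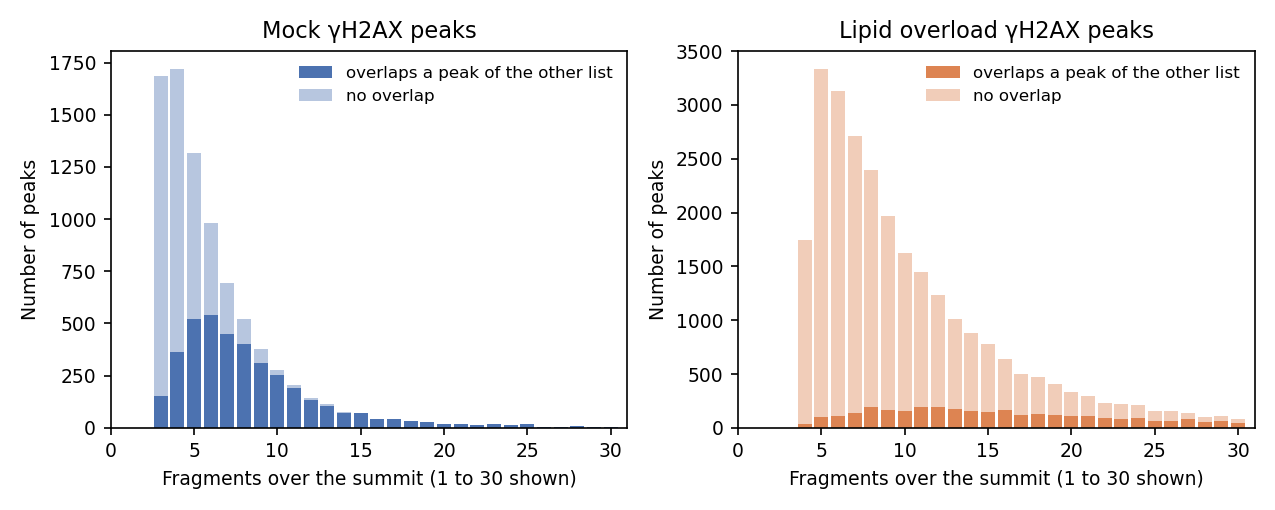
Number of peaks (vertical axis, scales differ) by fragments over the summit (horizontal axis, 1 to 30 shown) in the mock and the lipid-overload list, with dark bars for peaks that overlap a peak of the other list. Mock peaks pile up at 3 and 4 fragments, where 15.1% overlap a lipid-overload peak, and at 10 or more fragments 94.3% do. In the lipid-overload library, which is 2.62 times as deep so that the same fragment number marks a weaker site, 26.2% of peaks at 10 or more fragments overlap a mock peak.

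The first comparison asked where lipid overload places γH2AX relative to mock treatment. Lipid-overloaded cells had 3.20 times as many peaks as mock cells. Of the mock peaks, 3914 (45.8%, 44.8 to 46.9) overlapped a lipid-overload peak, against 0.521% for shuffled positions. Of the lipid-overload peaks, 3896 (14.3%, 13.9 to 14.7) overlapped a mock peak, against 0.168% for shuffled positions, and 23400 were in the lipid-overload list only. Sites with many fragments in mock were nearly always listed after lipid overload: 205 of the 207 mock peaks with 20 or more fragments overlapped a lipid-overload peak (99.0%, 96.6 to 99.9). In the other direction, at 2.62 times the depth, 1582 of the 3023 lipid-overload peaks with 20 or more fragments overlapped a mock peak (52.3%, 50.5 to 54.1). The 4628 peaks found only in mock were mostly weak, with a median of 4 fragments and 79.7% at 5 or fewer. Peaks found only in lipid overload had a median of 8 fragments, and shared ones 17. After thinning, 12070 lipid-overload peaks remained on average over 100 draws, 1.41 times the mock number (1.40 to 1.43 over the draws). Then 33.7% of the mock peaks overlapped a lipid-overload peak, and 23.6% of the lipid-overload peaks a mock peak. With lists of equal length the shares were 33.6% and 33.2%.

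Peaks of both γH2AX libraries were concentrated at the ends of protein-coding genes, with a larger share there in lipid overload. Shuffled positions, the only baseline here, do not allow for tagging of open chromatin as such. How much of this placing comes from γH2AX was not tested, since the IgG samples were not analysed. Chromosome Y, with 21 mock and 26 lipid-overload peaks, was left out of the shares by place, here and near chromosome ends. Peaks within 1 kb of a gene end made up 26.7% of the mock list (25.8 to 27.7), 31.0% of the lipid-overload list (30.5 to 31.6) and 28.3% of the peaks found only in lipid overload (27.7 to 28.9). Shuffled peaks fell there in 3.24%, 3.42% and 3.36% of cases. Shared mock peaks lay at gene ends in 47.2% of cases (45.6 to 48.8) and mock-only peaks in 9.43% (8.60 to 10.3). Peaks outside any annotated gene made up 25.0% of the mock list and 21.97% of the lipid-overload list, against 39.4% and 39.2% for shuffled peaks. After thinning, lipid-overload peaks at gene ends still outnumbered those of mock 2.16 times (2276 in mock, 4913 on average), while those away from gene ends outnumbered them 1.14 times. Gene ends then held 40.8% of the lipid-overload peaks and 37.4% of those found only there. Thinning cannot add the weak peaks that a shallower library would list. The 1.14 may therefore be too low and these shares too high.

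Of 19817 protein-coding genes, 2656 (13.4%, 12.9 to 13.9) had a gene-end peak in mock and 8610 (43.4%, 42.8 to 44.1) in lipid overload. Both lists marked 2390 genes, where independent lists of these lengths would share 1154. A gene-end peak in lipid overload only was listed for 6220 genes, and in mock only for 266. After thinning, 5569 genes had one in lipid overload on average, and 3634 in lipid overload only. For 556 genes the start is known from an adjoining divergent transcript, a noncoding RNA that runs away from the same promoter. In lipid overload 351 of these genes (63.1%, 59.0 to 67.2) had a peak at the 5′ end and 28 (5.04%, 3.37 to 7.20) at the 3′ end. In mock the counts were 111 (20.0%, 16.7 to 23.5) and 6 (1.08%, 0.397 to 2.33). These 556 genes are a selected set, marked more often than protein-coding genes at large. The contrast between their ends need not hold for all genes.

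The highest-ranked gene-end peaks of the lipid-overload list without a mock counterpart included those at SCLY, GART and MTMR12. SCLY, which releases selenium from selenocysteine, had 49 fragments over the summit (36.3 to 64.8) at chromosome 2, 238098408 to 238098683 (hg38). GART, an enzyme of purine synthesis, also had 49 fragments, at chromosome 21, 33542804 to 33543067, in a peak that reaches the neighbouring gene SON. A separate mock peak of 6 fragments (2.20 to 13.1) lay within 1 kb of the same end of GART. MTMR12 had 51 fragments (38.0 to 67.1), GPR108 50 (37.1 to 65.9) and VCL, which encodes the adhesion protein vinculin, 48 (35.4 to 63.6). FOSL2, a subunit of the AP-1 transcription factor, had 47 fragments (34.5 to 62.5) in a peak that also covers the antisense RNA FOSL2-AS1. UQCRC1, a subunit of respiratory complex III, had 41 (29.4 to 55.6) and the SUMO protease gene SENP2 40 (28.6 to 54.5). TMEM41B, an endoplasmic reticulum membrane protein, had 39 (27.7 to 53.3), and PPA1, an inorganic pyrophosphatase, had 38 (26.9 to 52.2).

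Other genes carried strong peaks in both conditions. TOMM40, the channel of the mitochondrial outer membrane import complex, had 113 fragments in mock (93.1 to 136) and 161 in lipid overload (137 to 188), at chromosome 19, 44890528 to 44891281 in the lipid-overload list. ELL, a transcription elongation factor, had 61 (46.7 to 78.4) and 116 (95.9 to 139), and the sugar transporter gene SLC2A8 39 (27.7 to 53.3) and 113 (93.1 to 136). FBXO31, whose end lies close to that of the autophagy gene MAP1LC3B, had 36 (25.2 to 49.8) and 100 (81.4 to 122). TAF11L3 had 39 and 72, PRR11, which shares its peak with the kinetochore gene SKA2, 31 and 48, PWWP2A 25 and 37, and the transcription factor gene HBP1 21 and 44. At 6 of these 8 genes the lipid-overload count was below 2.62 times the mock count, and SLC2A8 and FBXO31 were above it.

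The strongest gene-end peaks found only in mock were weak. PAXBP1 had 10 fragments (4.80 to 18.4), NHEJ1, an end-joining repair factor, 11 (5.49 to 19.7), LOC107987020 7 (2.81 to 14.4), the kinase gene MAP3K8 14 (7.65 to 23.5) and SHOC1 6 (2.20 to 13.1). Of these 5 genes, 3 had another peak at a gene end in lipid overload: 10 fragments at PAXBP1, 15 at NHEJ1 and 37 at MAP3K8.

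Among genes of lipid metabolism, those of cholesterol synthesis and uptake stood apart in mock, where 65% (40.8 to 84.6) had a gene-end peak. For fatty acid synthesis and lipid droplets the mock share was 7.69% (0.946 to 25.1). For fatty acid oxidation and PPAR targets it was 10% (1.23 to 31.7). In lipid overload the shares were 85% (62.1 to 96.8), 61.5% (40.6 to 79.8) and 40% (19.1 to 63.9) in this order, with overlapping intervals. No test between these lists was run. Of 26 genes of fatty acid synthesis and lipid droplets, 2 had a gene-end peak in mock and 16 in lipid overload. Random lists matched on gene length had medians of 3 and 12 (percentiles 20.2 and 95.6). The lipid droplet coat gene PLIN3 had 39 fragments in lipid overload (27.7 to 53.3), AGPAT2, which makes phosphatidic acid, 35 (24.4 to 48.7), the desaturase gene FADS2 31 (21.1 to 44.0), and ACACA, the carboxylase that starts fatty acid synthesis, 19 (11.4 to 29.7), all without a mock peak at a gene end. After thinning, 10.5 genes of this list remained on average (6 to 14 over the draws). Genes of cholesterol synthesis and uptake were marked already in mock, in 13 of 20, and in 17 of 20 after lipid overload, against medians of 3 and 10. The mock count lay above all 10000 random lists and the lipid-overload count at percentile 99.9. Of these genes, 11 had peaks in both lists, among them LSS with 9 fragments in mock and 46 in lipid overload and INSIG1 with 13 and 36. FDPS and HMGCS1, with 20 fragments each (12.2 to 30.9), CYP51A1 with 11 and MSMO1 with 10 had a gene-end peak in lipid overload only. DHCR7 and SC5D had one in mock only. The thinned count was 14.1 genes (10 to 17 over the draws). Fatty acid oxidation genes and PPAR targets stood at 2 and 8 of 20, near the random medians of 3 and 9. The 2 mock genes share 1 peak, and the highest peaks of the 8 genes were 7 different peaks. The thinned count was 5.29 genes (2 to 8 over the draws). CPT2 had 13 fragments (6.92 to 22.2), and ACADM and SLC25A20 11 each, in lipid overload only.

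Genes of endoplasmic reticulum stress and oxidative stress and immediate early genes were marked above the random lists in lipid overload. Inflammatory genes were not. High percentiles were not particular to stress genes, since ribosomal protein and housekeeping genes stood at 99.5 in lipid overload. In mock, endoplasmic reticulum stress genes stood as high already. Random lists were not matched on expression or CpG content. Of 20 genes of endoplasmic reticulum stress, 9 had a gene-end peak in mock and 15 in lipid overload. Random medians were 3 and 9 (percentiles 99.99 and 99.7). The chaperone gene HSPA5 was listed in both, with 9 and 32 fragments, and the chaperone gene CALR in lipid overload only, with 34 (23.5 to 47.5), as were SESN2 with 15, DNAJC3 with 14 and XBP1 with 8. Here and for the lists below, lipid overload only means without a mock peak at a gene end, and SESN2, DNAJC3, NR4A1 and DDB2 had a mock peak elsewhere in the gene. Of 20 oxidative stress genes, 5 were marked in mock and 16 in lipid overload. Random medians were 3 and 9 (percentiles 92.3 and 99.96). CAT, which encodes catalase, had 23 fragments (14.6 to 34.5), SOD1 16 and SRXN1 11 in lipid overload only. Immediate early genes, which cells switch on within minutes of a stimulus, numbered 6 and 16 of 20. Random medians were 2 and 8 (percentiles 98.4 and 99.995). NR4A1 had 32 fragments, DUSP1 30, KLF2 21 and KLF6 16 in lipid overload only. Inflammatory genes numbered 0 and 7 of 20, against random medians of 2 and 8 (percentiles 3.83 and 33.4). IRF1 had 25 fragments (16.2 to 36.9), SOCS3 15 and BIRC3 10 in lipid overload only. Thinned counts were 11.4 for endoplasmic reticulum stress (8 to 14 over the draws, which takes in the mock count of 9) and 9.92 for oxidative stress (6 to 15). They were 11.8 for immediate early (7 to 15) and 4.19 for inflammatory genes (1 to 7). Over all protein-coding genes the number went from 2656 in mock to 5569 after thinning. A rise in a list is therefore not by itself particular to that list.

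Genes of the DNA damage response were among those marked. Of 20 p53 targets, 8 had a gene-end peak in mock and 16 in lipid overload. Random medians were 3 and 9 (percentiles 99.7 and 99.9). In lipid overload only, the repair gene XPC had 29 fragments (19.4 to 41.6), DDB2 24, GADD45A 21 and TIGAR 19, while TP53I3 had 23 in mock and 52 in lipid overload. Of 22 genes of double-strand break signalling and repair, 7 and 16 were marked, against random medians of 3 and 10 (percentiles 98.1 and 99.4). H2AX, which encodes the histone mapped here, had 27 fragments (17.8 to 39.3), XRCC6 16, BRCA1 15 and PRKDC 14 in lipid overload only. Replication-dependent histone genes numbered 5 and 13 of 22 (percentiles 99.3 and 99.97), with H2BC5 at 13 fragments, H2AC8 at 12, and H2BC12 and H4C9 sharing 1 peak of 10, in lipid overload only. These short genes stand close together, and the highest peaks of the 5 and 13 genes were 3 and 9 different peaks. Among random lists not matched on length the percentiles were 88.5 and 92.3. Of 19 genes often altered in hepatocellular carcinoma, 2 and 11 were marked (percentiles 33.4 and 82.5), with ARID2 at 13 fragments (6.92 to 22.2) and CTNNB1 at 8 in lipid overload only. Thinned counts were 13.7 (11 to 16 over the draws), 11.98 (8 to 15), 8.75 (4 to 13) and 5.85 (2 to 9) for these 4 lists in turn. The ranges of the last 2 lists take in their mock counts of 5 and 2.

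Ribosomal protein and housekeeping genes, active in every cell, numbered 4 of 22 in mock and 15 of 22 in lipid overload (percentiles 76.5 and 99.5). TBP had 23 fragments (14.6 to 34.5), RPLP0 and GAPDH 19 each and B2M 12, in lipid overload only, and 8.86 genes remained on average after thinning. Hepatocyte genes rarely had a peak at a gene end. Of 22 genes for secreted liver proteins and liver transcription factors, 0 had a gene-end peak in mock and 1 in lipid overload (percentiles 2.35 and 0.01). That gene was CEBPA, with 18 fragments (10.7 to 28.4), and ALB, APOB and HNF4A had none there in either list. With peaks anywhere in the gene included, 2 of the 22 genes were marked in mock and 6 in lipid overload (percentiles 13.9 and 0.97). HNF4A then had 1 mock peak and 4 peaks found only in lipid overload. Markers of other cell types were as low, at 1 of 21 in each list (percentiles 14.4 and 0.005). The gene marked in lipid overload was COL1A1, with 9 fragments. Thinned counts were 0.79 for hepatocyte genes and 0.05 for the markers (0 to 1 over the draws for each).

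**Figure D2:**
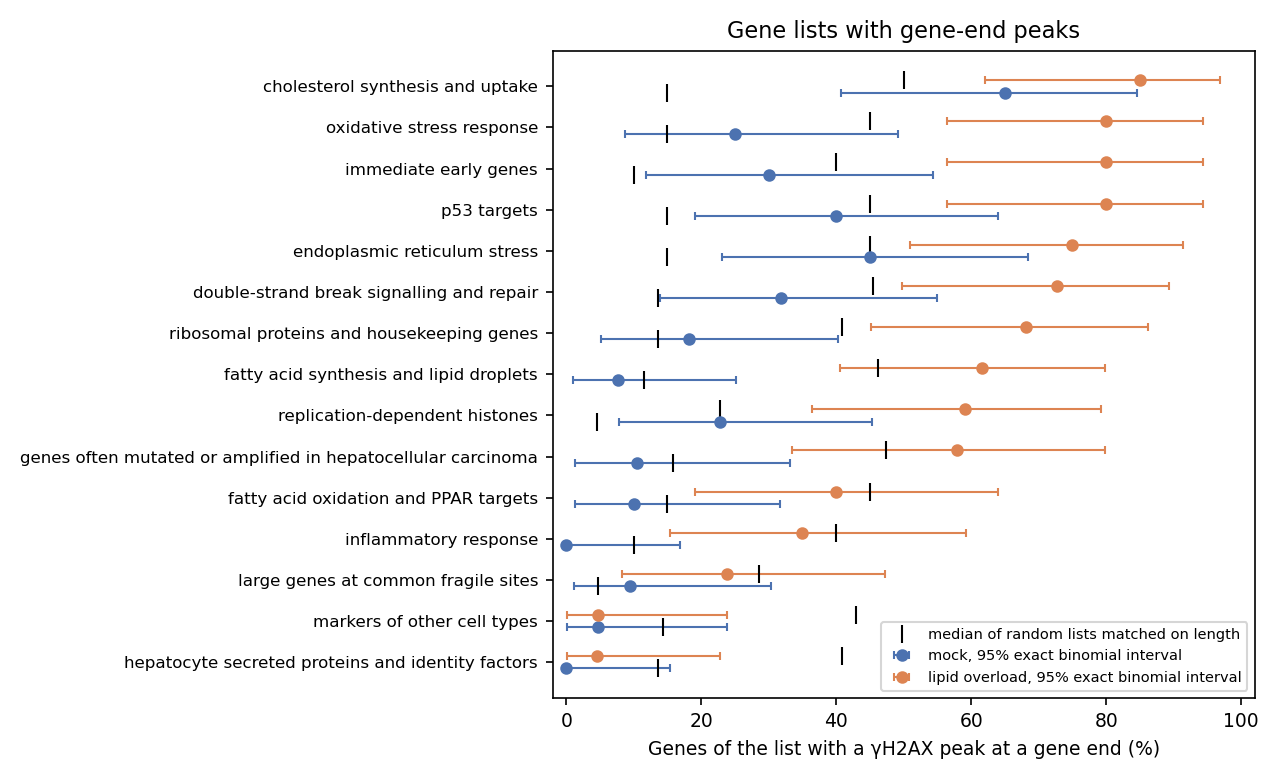
Share of each gene list (vertical axis) with a γH2AX peak within 1 kb of a gene end (horizontal axis, percent). Mock is blue and lipid overload orange, with exact 95% binomial intervals. Black bars give the median of random lists matched on gene length. Cholesterol genes were marked in 13 of 20 cases in mock already, and hepatocyte genes in 0 of 22.

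In lipid overload, large genes at common fragile sites held a peak about as often as random genes drawn from the same length bins. Genes in a bin differ in length, so the random genes need not be equally long. Parity with genes of equal length was not tested. Of 21 such genes, 7 held a mock peak and 13 a lipid-overload peak anywhere in the gene (percentiles 17.9 and 41.5 among random lists, which had a median of 13 in lipid overload). They held 13 mock and 38 lipid-overload peaks in all. DLG2, 2173 kb long, had 1 in mock and 6 in lipid overload, and NRXN3 1 and 5. No gene of this list held more than the 6 lipid-overload peaks of DLG2, while the median 1 Mb window held 4. As a set, these genes thus held few lipid-overload peaks for their length. In 6 genes peaks were listed in lipid overload only, led by AUTS2 with 3 peaks, the highest of 7 fragments (2.81 to 14.4), MACROD2 with 1 of 6 fragments, CSMD1 with 3 and LSAMP with 1. FHIT, 1504 kb long, and CNTNAP2, 2304 kb long, held no peak in either list.

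Lipid-only peaks were densest near the ends of some chromosomes. Mock peaks lay there as often: within 1 Mb of a chromosome end were 6.13% of the lipid-only peaks and 6.53% of the mock peaks. Shuffled peaks fell there in 1.61% and 1.57% of cases. The first 1 Mb of chromosome 5, which holds SDHA, AHRR and TRIP13, had 57 mock and 166 lipid-overload peaks, of which 120 were in lipid overload only. The median 1 Mb window held 1 mock and 4 lipid-overload peaks. Next came 136 to 137 Mb of chromosome 9, around NOTCH1 and AGPAT2, with 28 and 112 peaks, and 137 to 138 Mb of the same chromosome with 34 and 102. These 2 windows hold 37 and 39 coding genes, and the first Mb of chromosome 5 holds 14. The windows were not compared with others of equal gene number. The second Mb of chromosome 5, around TERT, the gene of the telomerase catalytic subunit, had 38 and 98. On chromosome 5 both lists were raised over much of the first 45 Mb, not only near its end. Among windows with 4 coding genes, 14 to 15 Mb held 10 and 39 peaks and 53 to 54 Mb held 1 and 4. Farther on, 133 to 134 Mb held 7 and 18. Copy number along this chromosome was not measured here. PTPRN2, 1049 kb long, held most peaks found only in lipid overload, 31 beside 7 mock peaks. RANBP2 followed with 28 over the 1123 kb the gene table gives it, then GSE1 with 27, DLGAP2 with 17, and AHRR and CUX1 with 15 each. Peaks were counted over the whole interval of a gene, so any at other genes within it are included. The length given for RANBP2 was not checked against another source. By length AHRR, the repressor of the aryl hydrocarbon receptor, was the densest of these 6 genes, at 12.9 per 100 kb.

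**Figure D3:**
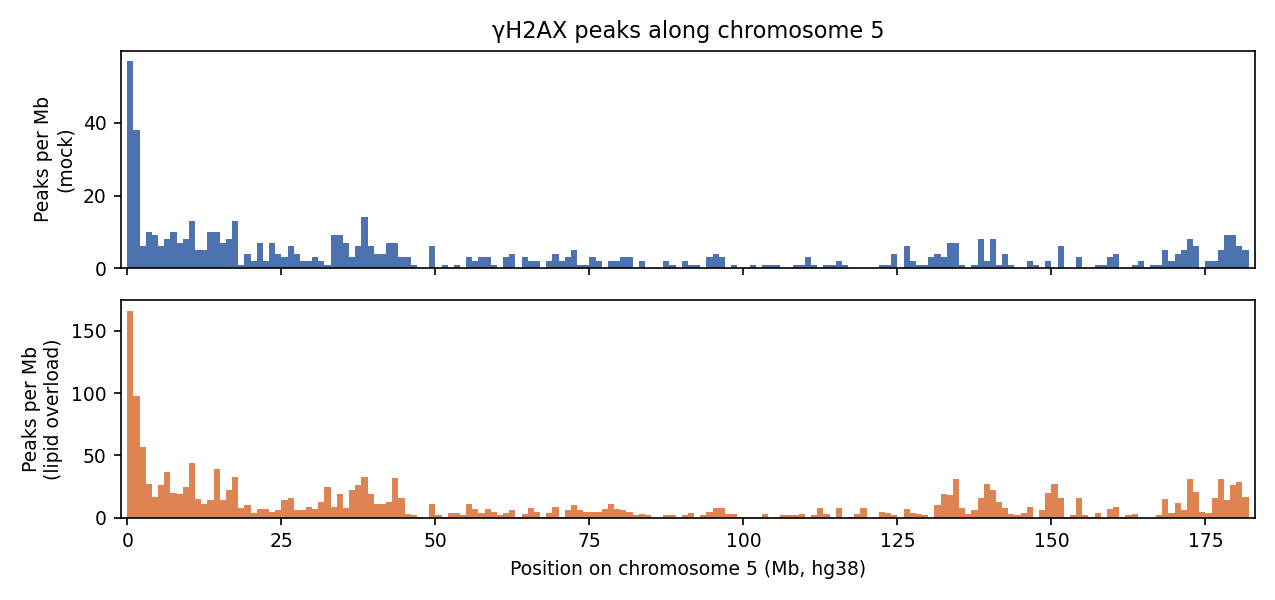
Number of γH2AX peaks per Mb (vertical axes, scales differ) along chromosome 5 (horizontal axis, Mb, hg38) in mock (top) and lipid overload (bottom). The first Mb held 57 mock and 166 lipid-overload peaks, the highest bar in both lists. Bars were also raised in both lists over much of the first 45 Mb.

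Away from gene ends, the highest-ranked peaks found only in lipid overload lay in noncoding RNA genes, inside a protein-coding gene or outside any gene. On chromosome 13, 44141911 to 44142331, a peak of 84 fragments (67.0 to 104) overlapped the noncoding RNAs LINC00390 and SMIM2-AS1. On chromosome 5, 1414384 to 1414557, a peak of 88 fragments (70.6 to 108) lay inside SLC6A3, the dopamine transporter gene. A peak of 64 fragments (49.3 to 81.7) on chromosome 2, 241953714 to 241953890, lay in LINC01237. The others overlapped no gene: 87 fragments (69.7 to 107) on chromosome 4, 49092746 to 49092905, and 106 (86.8 to 128) on chromosome 5, 49658626 to 49658776. The first lay near a very strong peak of both lists, at 49149336 of chromosome 4. The second had a fold of 9.83 despite its 106 fragments, so its local background was high. Whether these 2 sites are repeats was not examined.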

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

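Leaving out chromosome ends and thinning to the mock depth were chosen only after the result was seen. Lipid overload had a larger share of its peaks at gene ends than mock in every setting that gave both shares, and more peaks in every setting that gave their number. Equal list lengths set only the strongest lipid-overload peaks against the whole mock list. Stronger peaks lay at gene ends more often in both lists, so that setting favours lipid overload. Of 65 values recomputed, 24 stayed within 1.5 times a count or ratio or within the counting interval of a share, and 41 did not. Of the 24, 7 could not move: equal list lengths and thinning leave the mock share and the mock gene number untouched, and merging leaves the 3 gene numbers as they are. A −log10 q of at least 5 gave a ratio of peak numbers of 7.47, mock and lipid-overload overlaps of 88.2% and 11.8%, gene-end shares of 43.1% (mock), 48.7% (lipid overload) and 48.8% (lipid-overload only), and 762 genes with a mock gene-end peak. A fold of at least 5 gave overlaps of 69.8% and 16.3%, gene-end shares of 39.1%, 42.8% and 41.3%, and 1608 mock genes. Equal list lengths gave overlaps of 33.6% and 33.2%, gene-end shares of 51.8% (lipid overload) and 50.8% (lipid-overload only), 5127 lipid-overload genes and 3155 in lipid overload only, and no ratio, since both lists are then equally long. Merging peaks within 1 kb gave a lipid-overload overlap of 14.97% and gene-end shares of 30.0% and 26.8%. Overlap by 50% of each peak gave 28.3% and 8.87%, and 29.9% of lipid-only peaks at gene ends. Overlap within 1 kb gave 50.8%, 17.5% and 27.7% for the same values. Gene ends of 3 kb gave shares of 33.3%, 38.6% and 36.1%. Without peaks within 1 Mb of a chromosome end the overlaps were 44.2% and 13.8%, and the lipid-overload share at gene ends 31.8%. Thinned to the mock depth, the ratio was 1.41, the overlaps 33.7% and 23.6%, the gene-end shares 40.8% and 37.4%, and the gene numbers 5569 and 3634 (lipid overload only). Stricter and thinned settings use fewer peaks by construction, wider ends and looser overlap admit more, and the cause of the rest was not tested. Without matching on length, 27 of 30 list percentiles kept their side of the outer 2.5%. The immediate early list in mock moved to 97.5, and the histone list to 88.5 in mock and 92.3 in lipid overload. Depth limits the mock list most, where 55.3% of the peaks rest on 5 fragments or fewer.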

Other observations

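The tests by thinning, on chromosome copy number, on housekeeping genes, on fragment length and on repeats were chosen only after the result was seen, while that on fold was written before. The strongest γH2AX peaks stood in both libraries: all 50 highest-ranked mock peaks and 48 of the 50 highest-ranked lipid-overload peaks overlapped a peak of the other list. The highest peak of each list stood near the start of chromosome 5, at 11444 to 11723 in mock, with 234 fragments (205 to 266) in mock and 361 (325 to 400) in lipid overload. Others were on chromosome 4 at 49149336 (149 and 302 fragments), at the end of chromosome 1 at 248945689 (147 and 284), on chromosome 10 at 10228 (114 and 186), on chromosome 3 at 93470364 (150 and 219) and over the pseudogene DUX4L26 on chromosome 3 (114 and 217). Within 1 Mb of a chromosome end lay 6.53% of the mock peaks (6.01 to 7.07) and 6.64% of the lipid-overload peaks (6.34 to 6.94), against 1.57% and 1.63% for shuffled peaks. Of these 50 peaks, 25 lay there in mock and 22 in lipid overload.

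Peaks also ran together. The median distance to the next peak was 115 kb in mock, against 207 kb for shuffled peaks, and 26.8 kb in lipid overload, against 61.8 kb. Among the numbered chromosomes, lipid-overload peaks outnumbered mock peaks 3.74 times on chromosome 17, 3.62 times on chromosome 22 and 3.55 times on chromosome 19, but 2.31 times on chromosome 13, 2.56 times on chromosome 4 and 2.70 times on chromosome 18.

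Lipid overload had more γH2AX peaks than mock. The test on copy number of the chromosomes gained in HepG2 (2, 14, 16, 17 and 20) says little. Both libraries come from this line, so a shared gain would raise both lists. After thinning the ratio was 1.44 (1.34 to 1.55) on the gained chromosomes and 1.41 (1.35 to 1.46) on the others. An excess confined to the gained chromosomes is thus argued against. Copy number elsewhere, as along chromosome 5, was not measured. A limit of 1.5 was written beforehand for the ratio without thinning (3.15 on the other chromosomes, 3.35 on the gained ones). Depth alone passes it, with 1.83 to 1.86 for simulated equal sites. Fragment number alone is argued against too, since the ratio of all peaks stayed at 1.41 after thinning (1.37 to 1.46), where equal sites gave at most 0.965, though for peaks of 20 or more fragments it was 1.23 (0.987 to 1.53), which leaves these strong peaks open. Peaks with a fold of at least 5 had a ratio of 4.29, above the 1.5 set beforehand as arguing against depth or background, but that limit did not allow for fold growing with depth (simulated equal sites gave up to 2.54), and after thinning the ratio was 1.29 (1.21 to 1.36), where equal sites gave up to 1.02, which argues against depth alone but leaves background open. What stays open is lipid overload itself, which may raise γH2AX, or a difference in background between the single libraries, and without replicates these cannot be told apart.

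Gene ends gained more than other places after thinning, 2.16 against 1.14 times. Thinning only drops listed peaks and cannot add weak ones that a shallower library would list. Mock-only peaks, mostly weak, lay at gene ends in only 9.43% of cases, so the 1.14 may be too low. The simulation with equal sites was not split by place. Subtraction of an IgG control in only 1 library is argued against, since the fragment length inferred from the background differed from the narrowest peak by at most 0.563% in both libraries, as it would if each library served as its own background. More efficient tagging of open chromatin in the lipid-overload library may also raise gene ends, and cannot be told apart from lipid overload: housekeeping genes stood at 4 in mock and 8.86 after thinning (5 to 13 over the draws), a mean within the counting error of the mock number. A gain of γH2AX at promoters under lipid overload stays an open, untested explanation.

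Many of the strongest peaks lay near chromosome ends in both lists. Reads from repeats may collect on the few copies in the assembly. The 25 mock peaks near chromosome ends had a summed lipid-overload to mock ratio of 1.62 (1.53 to 1.71). The 21 shared peaks there among the 50 strongest of lipid overload had 1.68 (1.59 to 1.78), and both are below the library ratio of 2.62. A ratio below the library ratio and below those at gene ends had been written, after the result was seen, as the outcome for repeats. Collected reads may by themselves follow the library ratio, which was not tested. Lower values therefore do not decide for or against repeats. Peaks picked as strongest in mock also lean to a low ratio. Below 2.62 too were strong peaks elsewhere: the other 25 of the 50 strongest mock peaks had 1.74 (1.65 to 1.85), the 3 of these 50 at gene ends 1.64 (1.38 to 1.95), and the other 27 shared peaks among the 50 strongest of lipid overload 2.01 (1.89 to 2.13), which is above the 1.68 near chromosome ends. Whether the peaks elsewhere lie in repeats too was not examined, so they are no comparison free of repeats. All mock peaks of 20 or more fragments, most of them weaker, had 1.84 (1.78 to 1.89) away from gene ends and 2.40 (2.23 to 2.58) at gene ends. Repeats, peak strength itself and breaks at telomeres present in both conditions cannot be told apart, since the sequence of these sites was not used here.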
